A study of Mus musculus with 7899 samples.

How the data were processed

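Single sorted pancreatic cells of female C57BL/6J mice were sequenced with Smart-seq3xpress, a plate method that reads along whole transcripts. Per the labels' protocols, the pancreas was perfused with collagenase P, islets were picked by hand, dissociated with trypsin and sorted into plates by flow cytometry, and every cell is labelled as a β cell. The markers of the sort are not given in the sources used here. Each of 7897 samples is 1 cell, and 2 further samples are droplet libraries of whole islets that were not analysed here. The cells fall into 48 groups, and their labels name the biological replicate; the third replicates of G14.5, G18.5, P14L and high-fat-diet G14.5 are numbered in the same way without the word biological and were used as replicates. L and NL in the group names were read as lactating and not lactating, which the labels do not spell out.

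The authors deposited a count of reads per gene and cell for each of 7 sets of libraries, here called tables: a pregnancy time course, knockouts of Acss2, Stat3 and p300, high-fat diet, and islet cultures with A485 or nifuroxazide. Per the submitters' processing notes, Trimmomatic 0.39, featureCounts 2.0.1, Cell Ranger 3.1.0 and the genome GRCm38 (mm10) were used; the aligner and the gene annotation are not given in the sources used here. Whether duplicate reads were removed is not given there either. The deposited normalized values, a second unit, are reads divided by gene length and scaled by the authors so that all genes other than Ins1 and Ins2 sum to 100000 in each cell; this was checked on a sample of cells of each table. In the culture tables these sums ran from 74540 to 139173 with A485 and from 75872 to 154238 with nifuroxazide, so a further step was applied there that is not given in the sources used here. The deposited gene lengths in bases were used for that check alone. Normalized values were missing for 330 of 558 cells of the p300 table, which was not used in this unit, and for 587 of 970 cells of the Stat3 table. The Stat3 table held 12792 genes and that of p300 held 21177, against 21767 in the other tables, because both end before the last gene identifiers; 1 gene with missing values was left out of each. Ep300, Mafa and Ucn3 are not in the Stat3 table, and totals of both tables cover part of the genes. The tables hold no mitochondrially encoded genes and no ribosomal protein genes under the names searched, so these 2 quality lists could not be tested.

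Reads were summed over the cells of each group and replicate, which gave 100 libraries. Sums were normalized with TMM, genes with low counts were removed with filterByExpr on the groups, and 1 model per table was fitted with edgeR 4.0.16 (glmQLFit and glmQLFTest) under R 4.3.3. CPM values use the TMM library sizes, those of summed markers the plain ones, and are given as mean ± SD over replicates. Fold changes are on the log2 scale, with the standard error (SE) of the fit. A gene was called when its Benjamini-Hochberg adjusted p was under 0.05 within a comparison. There were 43 comparisons, all between groups of 2 or 3 replicates, and the p-values measure the spread between replicates labelled biological. Counting error alone does not cover the spread between mice, and reads without molecular identifiers are not independent molecules.

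The samples, comparisons, gene lists, named genes and alternatives were fixed before the data were examined, except where the text says otherwise. Of 16 fixed lists of pathway and quality genes, 14 had members in the tables and were tested with fry of limma 3.58.1, adjusted over the lists of a comparison. This test asks whether a list moves on balance one way and does not compare it with other genes. Beside it stand the members called over all genes tested and the members called when p-values were adjusted over the list alone. Another 8 lists hold markers of α, δ, PP, acinar, ductal, endothelial, immune and stromal cells. Some of these markers are also expressed in β cells: in both G0 libraries of the time course, 5 of 9 α-cell, 3 of 6 δ-cell, 2 of 2 PP-cell, 0 of 13 acinar, 2 of 7 ductal, 0 of 7 endothelial, 1 of 9 immune, 0 of 7 stromal and 1 of 30 hepatocyte markers reached 10 CPM. A list of 30 hepatocyte markers was written after 8 of them had appeared among the named genes; the other 22 were not looked at before. Gestation lists are the 916 genes higher and the 638 genes lower at G14.5 than at G0 in the pregnancy table, which were applied to the other 6 tables, whose libraries are different ones. For the time course itself the lists hold genes called in the same direction between wild-type G14.5 and G0 in at least 2 of the 3 knockout tables, 132 higher and 43 lower.

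Named genes follow a rule: Acss2, Tph1, Tph2, Prlr, Mki67, Ins1, Ins2, Mafa, Ucn3 and the targeted gene in each comparison; the 10 called genes with the highest and the 10 with the lowest fold change among those with a mean of at least 10 CPM and no overlap between the replicates of the groups; up to 4 called members of each fixed list with the smallest adjusted p; and the 5 genes with the smallest adjusted p in each interaction test. Other genes are named only where the text says that they were chosen after their values were seen. Positions are those of GENCODE M21 on GRCm38, in which all 407 named genes were found.

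For shares of cells, each cell was thinned to the 10th percentile of reads per cell of its table, 684889 reads in the pregnancy table, and 348 shallower cells were left out there. A cell was counted for the cell cycle when at least 3 of 23 cell cycle genes had a read. No 2 cells had identical reads.

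The alternatives were DESeq2 size factors in the edgeR fit, no filter on low counts, the Wald test of DESeq2 1.42.0, the replicate number as a block, each replicate left out in turn, gestation lists at 2-fold, limma on the mean deposited normalized values with 0.1 added before the logarithm, removal of cells with over 5% of their reads in Gcg, Sst, Ppy and Pyy, cell cycle shares from at least 2 genes, and shares without thinning. Shares from at least 12 genes were added after the data were seen, as were the block and the left-out replicates for the gestation lists outside the time course.

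The fit was tested on simulated data, with 67 genes changed 1.5-fold, 67 changed 2-fold and 66 changed 4-fold in 1 comparison of each table. It called 60.6% of the 4-fold and 40.3% of the 2-fold changes in the pregnancy table at G14.5. In the Acss2, Stat3 and p300 knockouts at G14.5 it called 71.2%, 65.2% and 68.2% of the 4-fold and 29.9%, 32.8% and 22.4% of the 2-fold changes. For high-fat-diet G14.5, A485 and nifuroxazide in maternal serum the shares were 57.6%, 62.1% and 62.1% at 4-fold and 34.3%, 22.4% and 28.4% at 2-fold. At 1.5-fold they ran from 3% in the Acss2, p300 and nifuroxazide tables to 13.4% in the pregnancy table. Genes that had not been changed made up 1.3% of calls in the pregnancy table, 8% for Acss2, 8.1% for Stat3, 19.5% for p300, 4.4% for high-fat diet, 6.2% for A485 and 12.7% for nifuroxazide, against a nominal 5%. fry gave p-values from 5.3e-14 to 0.000321 for 20 raised genes and from 0.163 to 0.741 for 20 unchanged genes. Results for some single genes are not reported here, so the members named for a list or cell type were not always all that passed.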

Results

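RNA was measured in 7897 single pancreatic β cells of mice sampled through gestation and after delivery, in mice with loss of Acss2, Stat3 or p300, on a high-fat diet, and in cultured islets. The pregnancy time course held 3481 cells of 16 groups: G0, which stands for gestation day 0, G3.5, G5.5, G6.5, G8.5, G10.5, G12.5, G14.5, G16.5 and G18.5, then days 2, 7 and 14 after delivery, each as L and NL, read as lactating and not lactating. The Acss2 and Stat3 tables held 1003 and 970 cells, knockout and wild type at G0, G14.5 and G18.5. The p300 table held knockout and wild type at G0 and G14.5. The high-fat-diet table held 1255 cells of 8 groups. The culture tables held 384 cells for A485 and 246 cells for nifuroxazide. G14.5, G18.5 and P14L of the time course and high-fat-diet G14.5 had 3 replicates, all other groups 2.

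Summed libraries held 25623339 to 181405413 reads in the pregnancy table, 42700922 to 126140264 in the Acss2 table, 26049748 to 154841243 in the Stat3 table and 26462938 to 136856415 in the p300 table. They held 18805394 to 129302954 reads in the high-fat-diet table, 13273435 to 55828413 in the A485 table and 17348728 to 40796202 in the nifuroxazide table. The median cell had 625088 reads in the A485 table and 1140722 in the p300 table, the lowest and highest of the 7 medians, and between 5874 and 8648 genes were detected in the median cell of a table. Ins1 and Ins2, the insulin genes, took 55.8% of reads in the time course, 60.1% and 60.7% in the Acss2 and Stat3 tables, and 46% and 41.5% in the cultures. Median log2 fold changes of all genes lay between -0.03 and 0.03 in every comparison.

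The stages of gestation were compared with G0 to follow how β cells adapt to pregnancy. At G14.5 the genes for serotonin synthesis were among those with the highest fold changes. Tph1 (ENSMUSG00000040046, chromosome 7, 46644641–46672537, minus strand), the rate-limiting enzyme of serotonin synthesis outside the brain, rose from 0.691 ± 0.212 CPM at G0 (n = 2) to 102.1 ± 15.3 CPM at G14.5 (n = 3), a log2 fold change of 7.12 (SE 0.81, adjusted p 4.39e-07). Its neuronal counterpart Tph2 rose by 4.89 on the log2 scale (SE 0.63, adjusted p 3.48e-06). Prlr, the prolactin receptor (chromosome 15, 10177238–10349180, plus strand), rose from 293 ± 70.7 to 1142 ± 119.8 CPM, a log2 fold change of 1.97 (SE 0.18, adjusted p 1.2e-08). Acss2, which makes acetyl-CoA from acetate, rose from 24.6 ± 4.51 to 35.5 ± 0.607 CPM (log2 fold change 0.53, adjusted p 0.0429). Its adjusted p was 0.112 with limma on mean deposited normalized values, 0.399 without G0 replicate 1, 0.0786 without G14.5 replicate 1, 0.0619 without G14.5 replicate 2 and 0.0895 without G14.5 replicate 3. The insulin genes Ins1 (0.09, adjusted p 0.791) and Ins2 (0.10, adjusted p 0.76), Ucn3 (-0.02, adjusted p 0.98) and Mki67, a marker of dividing cells (-0.23, adjusted p 0.976), did not pass the test. Mafa, at 1.27 and 2.87 CPM, was near the floor in both groups.

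In all, edgeR's quasi-likelihood test called 1554 of 15373 genes at G14.5, 916 higher and 638 lower, of which 293 and 220 changed at least 2-fold. Lactogen-responsive and pregnancy-associated islet genes moved up as a group (12 of 20 higher and 0 lower, 12 and 0 adjusted over the list alone, fry adjusted p 2.1e-08), with Cldn8, a claudin of tight junctions (6.76), Neb (5.31), Cish, a feedback inhibitor of cytokine signalling (4.26), and Matn2 (2.92). Outside the lists Sftpd (6.54), Crispld2 (6.10) and Fmo1 (4.60) rose. Protein entry into the endoplasmic reticulum rose (18 of 20 higher and 0 lower, 18 and 0 adjusted over the list alone, fry adjusted p 6.22e-05), among them Spcs1 (1.06). So did the unfolded protein response (12 of 20 higher and 0 lower, 14 and 0 adjusted over the list alone, fry adjusted p 0.000175), with Edem1 (1.36), and oxidative phosphorylation (10 of 24 higher and 0 lower, 13 and 0 adjusted over the list alone, fry adjusted p 0.00233), with Uqcrq (0.92). Amino acid response and one-carbon genes rose (7 of 20 higher and 0 lower, 10 and 1 adjusted over the list alone, fry adjusted p 0.00702), led by Nupr1 (1.83) and Phgdh (1.04). Exocytosis and excitability genes moved down (2 of 20 higher and 7 lower, 4 and 9 adjusted over the list alone, fry adjusted p 0.00124): the channel subunit Abcc8 fell (-0.56), whereas the granule protein Chgb rose from 732 ± 138.4 to 3938 ± 103.9 CPM. JAK-STAT genes moved up on balance (3 of 19 higher and 2 lower, 4 and 2 adjusted over the list alone, fry adjusted p 0.000102). Their median was 0.00 and their mean 0.35: Cish, Socs2 (1.94) and Prlr rose and Stat5a (-0.96) fell. Without G0 replicate 2 the adjusted p of the amino acid list was 0.0769. The count of genes at G14.5 was 920 without G0 replicate 1, 775 without G0 replicate 2 and 924 without G14.5 replicate 3.

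Of the other lists at G14.5, the fry test called none. Cell cycle genes had 4 of 23 higher and 0 lower, 5 and 0 adjusted over the list alone, fry adjusted p 0.289, and the 4 that passed were the replication genes Mcm2 (2.25), Rrm2 (2.56), Mcm6 (1.44) and Pcna (0.92). Members higher and lower, the same adjusted over the list alone, and the adjusted p were 3 and 0 of 20, 3 and 2, 0.344 for β-cell identity. There G6pc2 (1.40), Pcsk1 (0.79) and Isl1 (0.68) were higher. They were 2 and 5 of 24, 2 and 5, 0.4 for sterol and fatty acid synthesis, where Srebf1 (-0.89) and Fasn (-0.61) fell and Sqle (0.61) rose. They were 1 and 1 of 20, 2 and 3, 0.127 for histone acetyltransferases, deacetylases and acetyl-CoA genes, and 1 and 0 of 14, 1 and 0, 0.407 for genes kept low in mature β cells. They were 1 and 0 of 14, 1 and 0, 0.133 for the interferon response and 2 and 0 of 18, 3 and 0, 0.733 for immediate-early and heat-shock genes. Markers of other islet cells moved too. Sst, the δ-cell hormone, fell from 513 ± 348 to 95.5 ± 69.03 CPM (adjusted p 0.0459, 0.0574 with DESeq2 Wald test, 0.143 with limma on mean deposited normalized values, 0.397 without G0 replicate 1, 0.177 without G14.5 replicate 1, 0.078 without G14.5 replicate 2 and 0.255 without cells over 5% in other hormones). Of 9 α-cell markers Slc7a2, Gc and Ttr fell, and of 7 ductal markers Spp1 and Muc1 rose. The lists of mitochondrially encoded and of ribosomal protein genes had no members in any table. No marker of PP, acinar, endothelial, immune or stromal cells passed.

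**Figure D1:**
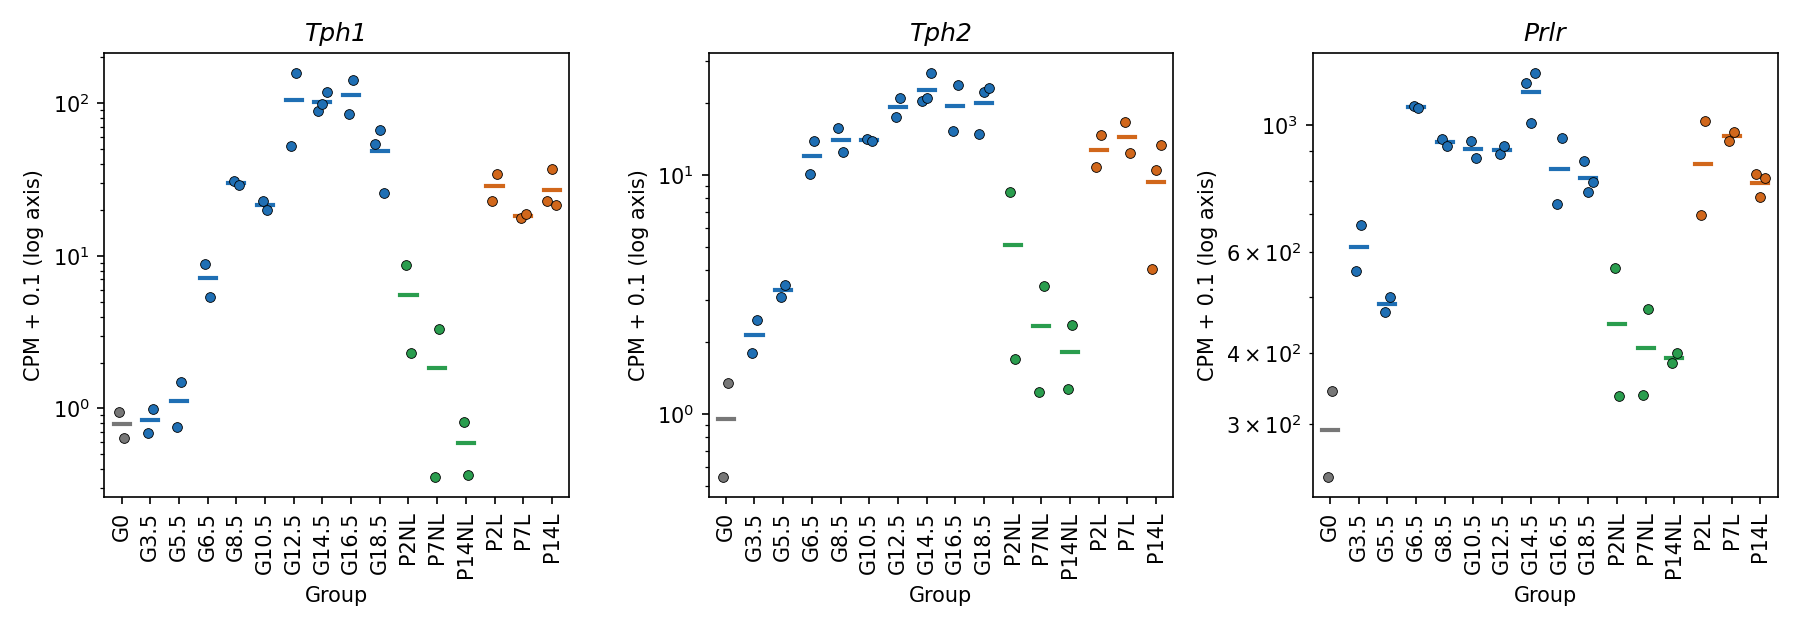
CPM plus 0.1 of Tph1, Tph2 and Prlr on a log axis against stage; points are libraries, bars group means, grey G0, blue gestation, green not lactating and orange lactating. Tph1 lies between 88.4 and 118.6 CPM in the 3 G14.5 libraries and at 0.841 and 0.541 CPM in the G0 libraries.

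The early stages were compared with G0 to find when the change began. At G3.5 Prlr had already risen to 613 ± 79.5 CPM (log2 fold change 1.07, SE 0.19, adjusted p 0.00404, n = 2; 0.0876 without G0 replicate 1 and 0.0544 without G3.5 replicate 2). Tph1 first passed the test at G6.5, at 7.04 ± 2.44 CPM (3.25, SE 0.78, adjusted p 0.0243, 0.124 without G0 replicate 1, 0.165 without G0 replicate 2 and 0.118 without G6.5 replicate 1), and lay at 0.738 ± 0.212 and 1.02 ± 0.516 CPM at G3.5 and G5.5. At G3.5, 65 genes were higher and 24 lower, with Gadd45b (3.06), Rgs2, a brake on G-protein signalling (2.66) and Txnip (1.81) higher and Nkx2-2 (-0.86) lower. At G5.5, 242 genes changed, 91 of them lower. Amino acid response and one-carbon genes rose there (6 of 20 higher and 0 lower, 14 and 0 adjusted over the list alone, fry adjusted p 0.00103), with the serine enzyme Phgdh (2.15). Lpl (-1.42) and Acly (-0.44) fell, and the sterol list was lower (0 of 24 higher and 2 lower, 0 and 5 adjusted over the list alone, fry adjusted p 0.0209). The adjusted p of that list was 0.199 without G0 replicate 2, 0.0777 without G5.5 replicate 1 and 0.146 without G5.5 replicate 2. At G6.5, 187 genes were higher and 67 lower: Tph2 (3.97), Cish (3.72) and Fmo1 (2.94) rose. The lactogen list moved up (8 of 20 higher and 0 lower, 11 and 1 adjusted over the list alone, fry adjusted p 0.000253), and so did the unfolded protein response (8 of 20 higher and 0 lower, 12 and 0 adjusted over the list alone, fry adjusted p 0.00333). The adjusted p of the latter was 0.0552 without G0 replicate 1 and 0.0559 without G6.5 replicate 1. The δ-cell markers summed to 2088 ± 2602 CPM at G6.5 against 573 ± 318 at G0, with Rbp4 called. Of 89 genes at G3.5, the count was 22 without G0 replicate 2, 35 without G3.5 replicate 1 and 51 without G3.5 replicate 2. Of 242 at G5.5, it was 43 without G0 replicate 2, 79 without G5.5 replicate 1 and 59 without G5.5 replicate 2. The count of 254 at G6.5 fell without any 1 library.

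The stages from G8.5 to G12.5 were compared with G0 to follow the rise. Tph1 stood at 29.9 ± 1.19, 21.4 ± 1.92 and 104.7 ± 74.4 CPM at G8.5, G10.5 and G12.5 (n = 2 each). It passed the test at each stage (adjusted p 8.23e-05, 0.000273 and 1.06e-06). The counts of genes higher and lower were 568 and 322 at G8.5 and 505 and 269 at G12.5, and at G10.5 424 genes changed, 292 of them higher. At G8.5 genes of hepatocytes had the highest folds: Mup3 stood at 30.8 against 0.0367 CPM at G0, and the serum albumin gene Alb at 162 ± 27.8 against 2.05 ± 0.927 CPM (log2 fold change 6.36). Of 30 hepatocyte markers 15 were called higher, 7 of them among the 22 markers not seen before the list was written, and 1 of the 30 reached 10 CPM in every G0 library. C1qa, of immune cells, rose at G8.5 and G12.5, and interferon genes at G8.5 (3 of 14 higher and 0 lower, 5 and 0 adjusted over the list alone, fry adjusted p 0.00667, 0.0533 without G8.5 replicate 1). The lactogen list was called at all 3 stages (adjusted p 8.19e-06, 1.79e-05 and 2.63e-07). Protein entry into the endoplasmic reticulum rose at G8.5 (11 of 20 higher and 0 lower, 17 and 0 adjusted over the list alone, fry adjusted p 0.000472), and the leucine enzyme Ivd (2.48) rose at G10.5. At G12.5 Acss2 passed (0.67, adjusted p 0.0302, 0.268 without G0 replicate 1, 0.0846 without G12.5 replicate 1 and 0.181 without G12.5 replicate 2). Immediate-early and heat-shock genes rose at G10.5 (3 of 18 higher and 0 lower, 7 and 0 adjusted over the list alone, fry adjusted p 0.005), with Jun (2.19) and Dnajb1 (1.56). At G8.5 the count was 363 without G0 replicate 2, 380 without G8.5 replicate 1 and 479 without G8.5 replicate 2. At G10.5 the count was 193 without G0 replicate 2, 0.321 times as high without G10.5 replicate 1 and 194 without G10.5 replicate 2. At G12.5 the count was 293 without G0 replicate 2, 364 without G12.5 replicate 1 and 351 without G12.5 replicate 2.

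Late gestation was compared with G0 as well. Tph1 stood at 113.2 ± 40.6 CPM at G16.5 (n = 2) and 48.7 ± 20.8 CPM at G18.5 (n = 3), with log2 fold changes of 7.26 (SE 0.83) and 6.05 (SE 0.79). At G16.5, 689 genes were higher and 425 lower, and at G18.5, 503 and 231. Lrrc8c, a subunit of volume-regulated anion channels (7.58), Crispld2 (7.005) and Cldn8 (6.89) had the highest folds at G18.5, and Gc, the vitamin D-binding protein and an α-cell marker (-1.98), fell. Sterol genes fell at G18.5 (0 of 24 higher and 3 lower, 1 and 7 adjusted over the list alone, fry adjusted p 0.0187). The adjusted p of the list was 0.196 without G0 replicate 2 and 0.0508 without G18.5 replicate 3. The lactogen list was called at both stages (adjusted p 1.89e-07 and 2.36e-08). At G16.5 the count was 425 without G0 replicate 2 and 407 without G16.5 replicate 2. At G18.5 the count was 348 without G0 replicate 2 and 444 without G18.5 replicate 3.

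Genes higher at G14.5 in wild-type mice of at least 2 of the 3 knockout tables, whose libraries are not in the time course, were followed to give the course on 1 scale. Their mean log2 level relative to G0 was 0.32 ± 0.18 at G3.5 and 0.24 ± 0.10 at G5.5, 1.14 ± 0.16 at G6.5, 2.40 ± 0.07 at G14.5 (n = 3) and 2.54 ± 0.07 at G18.5 (n = 3). After delivery it was 1.99 ± 0.48, 2.19 ± 0.0035 and 1.92 ± 0.15 on days 2, 7 and 14 in lactating mice, and 0.88 ± 0.33, 0.56 ± 0.31 and 0.29 ± 0.037 in mice not lactating. All of these genes lay above G0 at G14.5, and the fry adjusted p of the list was 2.14e-09.

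**Figure D2:**
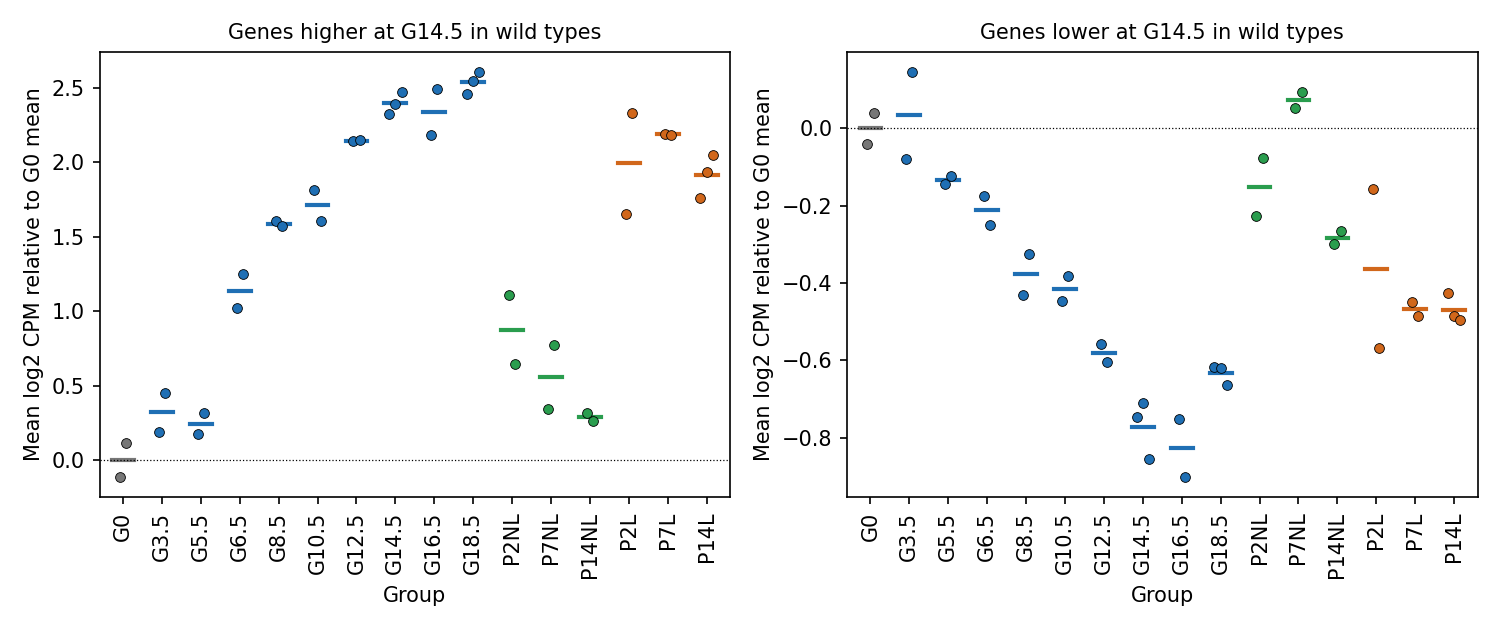
Mean log2 CPM of the genes higher and of the 43 genes lower at G14.5 in wild type of the knockout tables, relative to the G0 mean, by stage; points are libraries, bars group means, grey G0, blue gestation, green not lactating and orange lactating. The up list lies at 2.40 at G14.5, and on day 14 at 1.92 in lactating and 0.29 in non-lactating mice.

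Mice after delivery without lactation were compared with G0 to see what remained. Few genes were called: 74 higher and 14 lower on day 2, 57 and 14 on day 7, and 23 and 20 on day 14. On day 2 Tph2 (2.71, adjusted p 0.0279, 0.26 without G0 replicate 1, 0.0529 without G0 replicate 2 and 0.806 without P2NL replicate 1), Fmo1 (2.19) and Matn2 (1.80) were still higher, whereas Tph1 (2.87, adjusted p 0.083) and Prlr (0.62, adjusted p 0.146) did not pass. By day 14 Tph1 was at 0.490 ± 0.319 CPM against 0.691 ± 0.212 CPM at G0 (n = 2 each). Phgdh (1.67), Nupr1 (1.63) and G6pc2 (0.83) remained higher on day 14. The lactogen list was called on day 2 (4 of 20 higher and 0 lower, 10 and 0 adjusted over the list alone, fry adjusted p 0.00438), with an adjusted p of 0.0682 without P2NL replicate 1. Immediate-early genes were higher on day 2 (2 of 18 higher and 0 lower, 7 and 0 adjusted over the list alone, fry adjusted p 0.00438). The α-cell marker Gc fell on day 7 (-1.25). On day 2 the count was 32 without G0 replicate 2, 15 without P2NL replicate 1 and 47 without P2NL replicate 2. On day 7 the count was 46 without G0 replicate 1, 10 without G0 replicate 2 and 1 without P7NL replicate 2. On day 14 the count was 95 without G0 replicate 1, 3 without G0 replicate 2, 17 without P14NL replicate 1 and 10 without P14NL replicate 2.

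Lactating and non-lactating mice of the same day were compared to ask whether lactation prolongs the gestational state. On day 14 Tph1 stood at 27.1 ± 8.46 CPM in lactating mice (n = 3) and 0.490 ± 0.319 CPM in the others (n = 2), a log2 fold change of 5.81 (SE 0.74, adjusted p 1.26e-05). On day 7 it stood at 18.1 ± 0.807 and 1.73 ± 2.08 CPM (3.58, SE 0.69, adjusted p 0.00375, n = 2 each, 0.115 without P7NL replicate 1). Prlr was higher on days 2, 7 and 14 (0.93, 1.23 and 1.02; adjusted p 0.025, 0.000251 and 0.00117), on day 2 with 1 without P2L replicate 2 and 1 without P2NL replicate 2. On days 2 and 14, 17 and 94 genes were higher in lactating mice and 2 and 17 lower, and on day 7 82.9% of the genes called were higher and 22 lower. Sftpd (6.03 and 5.62), Cldn8 (4.47 and 4.76) and Chgb (2.14 and 1.88) were higher on days 7 and 14, and Ivd rose on day 2 (1.77). The zinc transporter Slc30a8 (-0.52 and -0.64) fell on both days, as did the α-cell marker Ttr (-1.01 on day 14). The lactogen list rose on day 7 (10 of 20 higher and 0 lower, 12 and 2 adjusted over the list alone, fry adjusted p 1.38e-05) and day 14 (9 of 20 higher and 0 lower, 13 and 1 adjusted over the list alone, fry adjusted p 2.87e-05). It rose on day 2 (3 of 20 higher and 0 lower, 11 and 1 adjusted over the list alone, fry adjusted p 0.00877) with an adjusted p of 0.24 without P2L replicate 2 and 0.34 without P2NL replicate 2. Days 7 and 14 shared 60 of their higher genes, against 0.654 by chance, and 88 genes higher on day 7 were also higher at G14.5 than at G0, against 6.38 by chance. These comparisons share no library. C1qa rose on day 14. On day 2 the count was 58 without P2L replicate 1, 0 without P2L replicate 2 and 0 without P2NL replicate 2. On day 7 the count was 63 without P7L replicate 1, 58 without P7L replicate 2, 41 without P7NL replicate 1 and 53 without P7NL replicate 2. On day 14 the count was 48 without P14NL replicate 1 and 56 without P14NL replicate 2.

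Shares of cells in the time course, at 1 depth per cell, were taken to ask how many cells carried the transcripts. Tph1 reads were found in 33.9% and 23.8% of cells in the G0 libraries, in 91.1%, 92% and 95% in the G14.5 libraries, and in 8.6% and 14% in the day 14 libraries without lactation. Tph2 reads were found in 11.9% and 19% of cells at G0 and in 72.3%, 70.1% and 62.4% at G14.5. Reads of the acinar gene Prss2, which β cells should lack, were found in 0 to 28.4% of cells of a library, with the highest share in G6.5 replicate 2, and those of the α-cell hormone Gcg in 98.7% to 100%. At least 3 cell cycle genes had a read in a mean of 50.5% of cells at G0 and 68.5% at G14.5, with group means from 42.7% at G5.5 to 69.8% at G8.5 and G0 libraries at 67.8% and 33.3%. With at least 12 genes, chosen after the data were seen, no time-course group mean passed 4.15%. No test was made on shares.

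Knockout of Acss2 was compared with wild type at each stage to ask what the gene does in β cells. Acss2 (chromosome 2, 155517948–155585724, plus strand) stood at 11.3 and 9.757 CPM in the G0 knockout libraries against 18 and 26.07 in wild type. It stood at 17.86 and 19.03 against 25.46 and 38.5 at G14.5, and at 21.67 and 15.75 against 27.31 and 32.24 at G18.5. The log2 fold changes of -1.06 (SE 0.25), -0.79 (SE 0.24) and -0.67 (SE 0.24) did not pass the test (n = 2 per group). At G14.5 Chac1, an enzyme that breaks down glutathione and is switched on by stress (ENSMUSG00000027313, chromosome 2, 119351229–119354381, plus strand), fell to 21.5 ± 0.835 from 78.2 ± 15.8 CPM in wild type (-1.87, adjusted p 0.00161), also without any 1 library. G14.5 wild-type replicate 2 held 1020 CPM of hepatocyte markers, whose median log2 fold change in this comparison was -5.10, with none of 29 called. P2ry1, a receptor for extracellular ADP (chromosome 3, 61002795–61008982, plus strand), fell to 39.01 ± 0.807 from 95.2 ± 9.16 CPM (-1.29, adjusted p 0.003, 0.11 without G14.5 knockout replicate 1 and 0.0835 without G14.5 knockout replicate 2). The only other gene of 14057 that passed, named after the values were seen, was Fbxw18, which was lower. Tph1 (-0.30, adjusted p 0.826) and Prlr (-0.04, adjusted p 0.973) were not called. At G0 the test called 1 gene, Sftpd, higher at 0.697 against 0.0144 CPM. At G18.5, 11 genes were higher and 10 lower: the immediate-early genes Npas4 (3.56), Fosb (2.56) and Fos (1.42) rose, as did Gdf3 (6.41). Pianp stood at 28.5 against 0.0147 CPM, but was also high in wild type of the p300 table. The chaperones Hsph1 (-1.19) and Dnajb9 (-0.95) fell. Genes for protein entry into the endoplasmic reticulum were lower at G18.5 (0 of 20 higher and 0 lower, 0 and 15 adjusted over the list alone, fry adjusted p 0.0406), with an adjusted p of 0.0887 with the replicate block, 0.279 without G18.5 knockout replicate 1, 0.0686 without G18.5 wild-type replicate 1 and 0.253 without G18.5 wild-type replicate 2. At G0 the count was 3 without G0 knockout replicate 1, 2 without G0 knockout replicate 2 and 5 without G0 wild-type replicate 1. At G14.5 the count was 40 without G14.5 wild-type replicate 1 and 19 without G14.5 wild-type replicate 2. At G18.5 the count was 54 without G18.5 knockout replicate 2, 83 without G18.5 wild-type replicate 1 and 7 without G18.5 wild-type replicate 2.

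The knockout effect at G14.5 was tested against that at G0 to ask whether it depends on gestation. For 3 genes the 2 effects differed: Sftpd (-5.46, adjusted p 0.00833), P2ry1 (-1.52, adjusted p 0.0254) and Chac1 (-2.01, adjusted p 0.0254). Chac1 stood at 27.2 and 24.6 CPM in knockout and wild type at G0, and at 21.5 and 78.2 CPM at G14.5. The interaction of Chac1 had an adjusted p of 0.0958 without G0 knockout replicate 1, 0.0687 without G0 knockout replicate 2, 0.0564 without G0 wild-type replicate 1, 0.163 without G0 wild-type replicate 2, 0.178 without G14.5 knockout replicate 1 and 0.162 without G14.5 knockout replicate 2. That of P2ry1 was 0.0953 without G0 knockout replicate 1, 0.171 without G0 knockout replicate 2, 0.0516 without G0 wild-type replicate 1, 0.202 without G0 wild-type replicate 2, 0.182 without G14.5 knockout replicate 1 and 0.162 without G14.5 knockout replicate 2. The number of genes was 1 without G0 knockout replicate 1, 1 without G0 knockout replicate 2, 1 without G0 wild-type replicate 2, 1 without G14.5 knockout replicate 1, 1 without G14.5 knockout replicate 2, 28 without G14.5 wild-type replicate 1 and 5 without G14.5 wild-type replicate 2. Hepatocyte markers had a median of -5.35. In wild type G14.5 itself differed from G0 in 410 genes, 283 of them higher (177 without G0 wild-type replicate 1). Tph1 stood at 179 against 0.0575 CPM, Prlr rose by 1.49 and Chgb by 2.89. The lactogen list rose (12 of 20 higher and 0 lower, 14 and 0 adjusted over the list alone, fry adjusted p 0.000103) and sterol genes fell (0 of 24 higher and 5 lower, 0 and 9 adjusted over the list alone, fry adjusted p 0.00281). The α-cell marker Slc7a2 and Ppy, the PP-cell hormone (-2.09), fell, and C1qa rose. Of the genes higher, 203 were also higher at G14.5 in the time course, with a Fisher p of 5.6e-181 and no library shared.

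**Figure D3:**
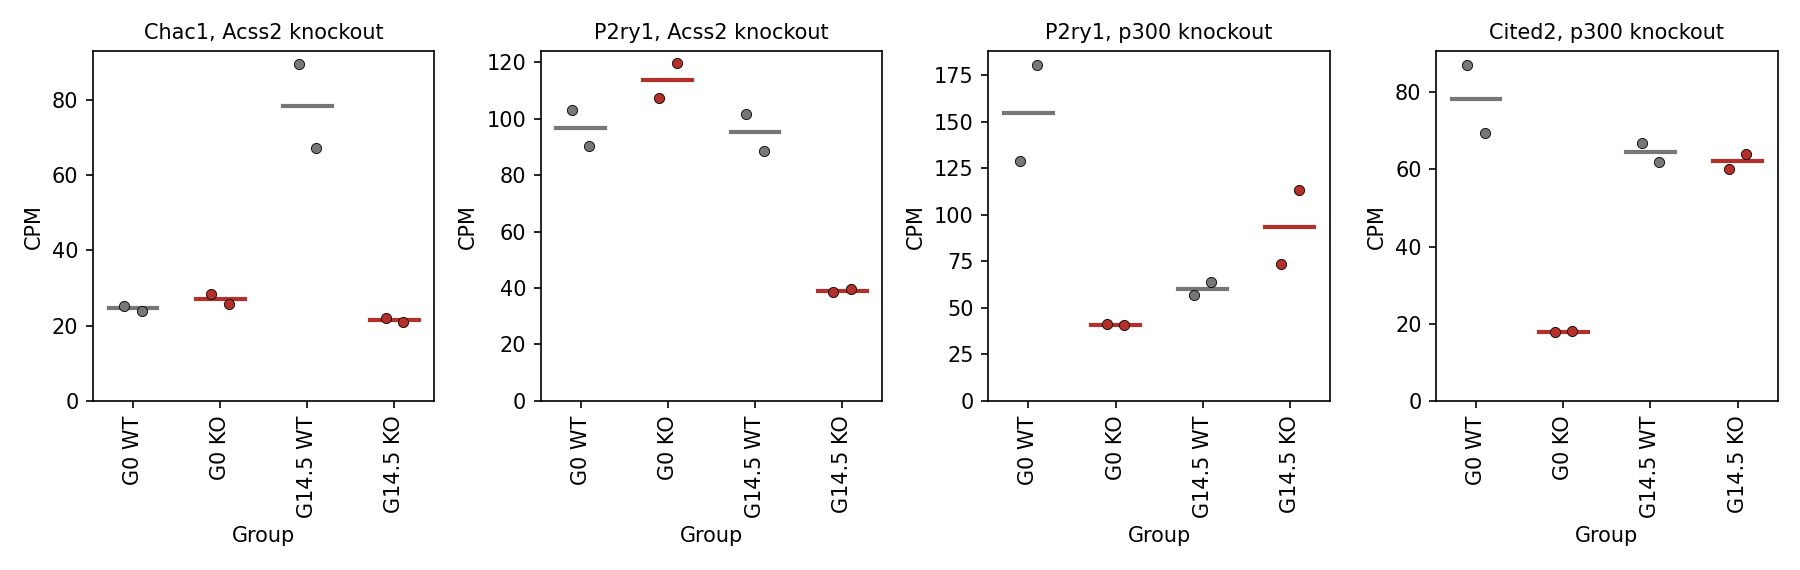
CPM of Chac1 and P2ry1 in the Acss2 table and of P2ry1 and Cited2 in the p300 table, by stage and genotype; points are libraries and bars group means. Chac1 lies at 21.5 CPM in G14.5 knockout and 78.2 CPM in G14.5 wild type.

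Knockout of Stat3, a transcription factor of cytokine signalling, was compared with wild type to ask what it controls. Stat3 (chromosome 11, 100885098–100939540, minus strand) stood at 66.09 and 49.36 CPM in the G0 knockout libraries against 65.88 and 70.79 in wild type, so knockout replicate 1 lay above a wild-type library. It stood at 67.37 and 73.67 against 80.34 and 90.23 CPM at G14.5, and at 60.73 and 67.45 against 78.26 and 86.5 CPM at G18.5. None of the log2 fold changes of -0.24, -0.27 and -0.36 passed the test. At G14.5 Iqgap2, a scaffold of the cytoskeleton, rose by 2.76 (SE 0.40, adjusted p 0.035, 0.593 with limma on mean deposited normalized values, 0.0666 without G14.5 wild-type replicate 1 and 0.151 without G14.5 wild-type replicate 2). At G18.5 Dct (-2.11, adjusted p 0.00379) and the inflammatory regulator Nfkbiz (-1.998, adjusted p 0.00379) fell. At G0 edgeR called 0 of 10207 genes, with 830 at unadjusted p < 0.05 and 84 by DESeq2, and for the interaction 0, with 809 and 49. Tph1 at G14.5 did not pass (-0.83, adjusted p 0.633), with 260.5 ± 29.6 CPM in wild type. In wild type 178 genes differed between G14.5 and G0, 49 of them lower: Tph1 (10.89), Chgb (2.84) and Prlr (1.14, adjusted p 0.00369, 0.06 without G0 wild-type replicate 1) rose. Acss2 rose as well (1.29, adjusted p 0.013, 0.15 without G0 wild-type replicate 2 and 0.0823 without G14.5 wild-type replicate 1). The lactogen list was higher (8 of 16 higher and 0 lower, 11 and 0 adjusted over the list alone, fry adjusted p 0.000173). C1qa rose too. G14.5 wild-type replicate 2 held 828.4 CPM of hepatocyte markers, whose median log2 fold change was -8.89 in the knockout comparison at G14.5, with none of 19 called. At G0 the count was 8 without G0 knockout replicate 1, 28 without G0 knockout replicate 2, 21 without G0 wild-type replicate 1 and 2 without G0 wild-type replicate 2. At G14.5 the count was 7 without G14.5 knockout replicate 1, 2 without G14.5 knockout replicate 2, 12 without G14.5 wild-type replicate 1 and 0 without G14.5 wild-type replicate 2. At G18.5 the count was 5 without G18.5 knockout replicate 1, 5 without G18.5 knockout replicate 2 and 7 without G18.5 wild-type replicate 1. For the interaction the count was 2 without G0 knockout replicate 1, 12 without G0 knockout replicate 2, 4 without G0 wild-type replicate 1, 1 without G0 wild-type replicate 2, 5 without G14.5 wild-type replicate 1 and 1 without G14.5 wild-type replicate 2. In wild type the count fell without any 1 library.

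Knockout of p300, the acetyltransferase encoded by Ep300, was compared with wild type to ask which genes need it. Ep300 (chromosome 15, 81585351–81652077, plus strand) stood at 15.93 and 11.95 CPM in the G0 knockout libraries against 24.24 and 36.69 in wild type (-1.13, SE 0.26, adjusted p 0.0524). It stood at 20.37 and 19.7 against 27.5 and 37.22 CPM at G14.5 (-0.69, adjusted p 0.369). At G0, 207 genes differed in knockout, 64 of them higher. Rgs2 stood at 16.6 against 449 CPM (-4.76, SE 0.46, n = 2 each). Wild-type G0 was low too in the time course but not in the Acss2 and Stat3 tables, so a wild-type difference was not excluded. The incretin-linked receptor Gpr119 (-3.39), the feedback inhibitors Cish (-2.47) and Socs2 (-0.995), and the acetyltransferase gene Kat2b (-0.99) fell. The chaperones and folding enzymes Hspa5 (0.76) and Pdia4 (1.13) and the secretory-cell factor Bhlha15 (1.54) rose. The lactogen list was lower (0 of 20 higher and 5 lower, 0 and 11 adjusted over the list alone, fry adjusted p 0.0284), but was not called with any 1 library left out. The ductal marker Krt18 rose and C1qa fell. The count at G0 fell when either knockout library was left out. At G14.5 edgeR called 0 of 13475 genes, with 1333 at unadjusted p < 0.05 and 294 by DESeq2 (1 without G14.5 knockout replicate 1, 13 without G14.5 knockout replicate 2, 32 without G14.5 wild-type replicate 1 and 1 without G14.5 wild-type replicate 2), and Tph1 stood at 132.5 ± 8.40 CPM in knockout and 158.7 ± 28 CPM in wild type.

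The p300 effect differed between G14.5 and G0 for 9 genes, 8 with a higher and 1 with a lower effect at G14.5. Among them was P2ry1, at 40.9 against 154.8 CPM in knockout and wild type at G0 and 93.4 against 60.3 CPM at G14.5 (2.55, adjusted p 0.0109, 0.0527 without G0 knockout replicate 2). Another was Cited2, which competes for p300 (chromosome 10, 17723218–17725674, plus strand), at 17.9 against 78.3 and 62.1 against 64.5 CPM (2.07, adjusted p 0.0109, 0.057 without G0 knockout replicate 2). In wild type 290 genes differed between G14.5 and G0, 169 of them higher. This count and that of the interaction varied widely with 1 library left out. Tph1 (7.92), Chgb (2.76), Dlx5 (6.10) and Prlr (0.85, adjusted p 0.0207, 0.0526 without G14.5 wild-type replicate 2) rose, with the lactogen list (11 of 20 higher and 1 lower, 13 and 1 adjusted over the list alone, fry adjusted p 0.00221). The hormones of other islet cells fell: Gcg (-5.69), Sst (-4.73), Pyy (-6.60) and Ppy (-4.99). Gcg reads were found in 76% and 100% of cells in the G0 libraries and 4.4% and 25% at G14.5. In the time course it was 98.7% to 100%. Hepatocyte markers had a median of -4.76. Gestation was not told apart from a difference between libraries.

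**Figure D4:**
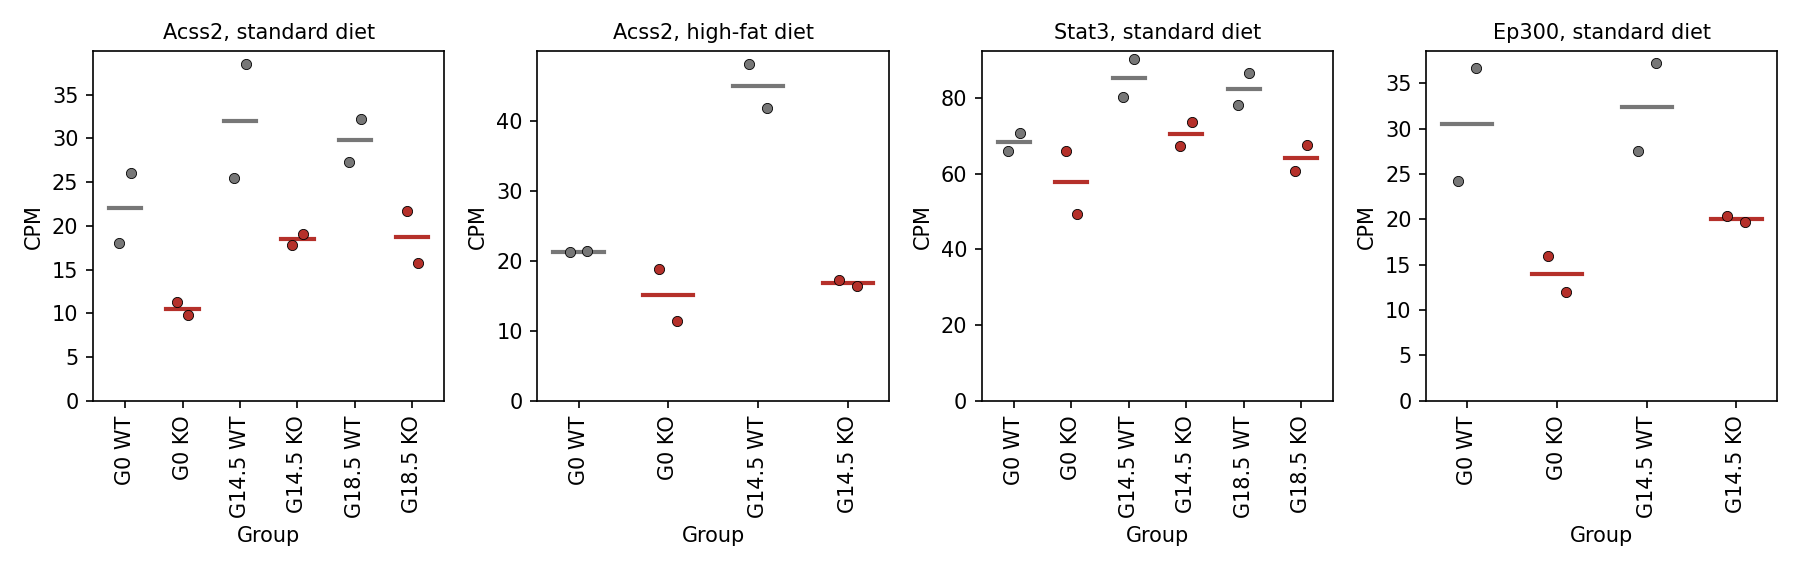
CPM of the targeted gene in each knockout table and of Acss2 in the high-fat-diet table, by stage; points are libraries, grey wild type and red knockout. In the high-fat-diet table Acss2 lies at 17.3 and 16.37 CPM in G14.5 knockout and 48.09 and 41.85 CPM in wild type.

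Mice on a high-fat diet were compared across stages to ask whether gestation acts in the same way under it. Tph1 rose to 106.5 ± 2.53 CPM at G14.5 (n = 3) from 0.929 ± 0.2498 CPM at G0 (n = 2), a log2 fold change of 6.82 (SE 0.77, adjusted p 0.000342). Tph2 (2.27, adjusted p 0.298) and Acss2 (0.68, adjusted p 0.0934) did not pass. Prlr rose (0.95, adjusted p 0.0171, 0.061 with the replicate block, 0.0509 without HFD G0 replicate 1, 0.33 without HFD G0 replicate 2 and 0.0543 without HFD G14.5 replicate 3). In all 275 genes changed, 172 of them higher. Sftpd (6.85), Cldn8 (5.34) and Chgb (1.97) rose, and Rgs2 (-3.47), the metallothioneins Mt1 (-1.56) and Mt2 (-1.65), the glucose transporter Slc2a2 (-0.80) and Iapp (-1.14) fell. These last 4 did not pass with the replicate block (lowest adjusted p 0.061), where 95 genes did, nor with limma (lowest 0.0548). The lactogen list rose (8 of 20 higher and 1 lower, 12 and 2 adjusted over the list alone, fry adjusted p 0.00678), with an adjusted p of 0.111 without HFD G0 replicate 2. The α-cell marker Slc7a2 fell and the ductal Krt18 rose. Of the genes higher, 110 were also higher at G14.5 in the time course, against 11.2 by chance. On day 7 after delivery without lactation edgeR called 0 of 14115 genes, with 759 at unadjusted p < 0.05 and 34 by DESeq2. Tph1 was near G0 (0.90, adjusted p 0.94). At G14.5 the count was 0.433 times as high without HFD G0 replicate 1, 7 without HFD G0 replicate 2, 168 without HFD G14.5 replicate 1 and 86 without HFD G14.5 replicate 3. On day 7 the count was 1 without HFD G0 replicate 1, 4 without HFD G0 replicate 2 and 1 without HFD P7NL replicate 1.

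Acss2 knockout on the high-fat diet was compared with wild type to ask whether diet brings out an effect. Acss2 stood at 18.77 and 11.46 CPM in the G0 knockout libraries against 21.24 and 21.43 in wild type (adjusted p 0.623). It stood at 17.3 and 16.37 against 48.09 and 41.85 CPM at G14.5, where it fell (-1.42, SE 0.22, adjusted p 0.012, 0.221 without HFD G14.5 knockout replicate 1, 0.401 without HFD G14.5 knockout replicate 2 and 0.0912 without HFD G14.5 wild-type replicate 1). At G14.5 Ivd, an enzyme of leucine breakdown (ENSMUSG00000027332, chromosome 2, 118861954–118882909, plus strand), fell to 154.1 ± 9.13 from 568 ± 60.6 CPM (-1.88, adjusted p 0.00425, 0.0712 without HFD G14.5 knockout replicate 1 and 0.135 without HFD G14.5 knockout replicate 2). Rbp4, a retinol carrier also used as a δ-cell marker (-2.83), Fam151a (-2.18) and Grcc10 (-1.08) fell. Grcc10 was not called with any 1 library left out, and had adjusted p 0.0518 with RLE size factors and 0.0976 with the replicate block. Pianp (chromosome 6, 124996694–125003096, plus strand) stood at 32.3 against 0.0636 CPM, but was also high in wild type of the p300 table. The others of the 9 genes called, named after the values were seen, were Slc39a7, Pcp4l1 and Gm10076. Tph1 (-1.25, adjusted p 0.588) did not pass. For Ivd (-2.47, adjusted p 0.00979, 0.0725 without HFD G14.5 knockout replicate 2) and Pianp the effect at G14.5 differed from that at G0. At G0 edgeR called 0 genes, with 1094 at unadjusted p < 0.05 and 78 by DESeq2. The δ-cell markers summed to 160.1 CPM in G14.5 knockout and 711.8 ± 657.1 in wild type, and acinar markers to 250.5 ± 340.1 and 7.974 ± 7.843 CPM. Gcg reads were found in 73% and 70.7% of cells in the G14.5 knockout libraries and in 100% in both wild-type libraries. At G0 the count was 91 without HFD G0 knockout replicate 1, 14 without HFD G0 wild-type replicate 1 and 1 without HFD G0 wild-type replicate 2. At G14.5 the count was 0 without HFD G14.5 knockout replicate 1, 0 without HFD G14.5 knockout replicate 2, 4 without HFD G14.5 wild-type replicate 1 and 5 without HFD G14.5 wild-type replicate 2. For the interaction the count was 20 without HFD G0 knockout replicate 1, 7 without HFD G0 wild-type replicate 1, 4 without HFD G0 wild-type replicate 2, 1 without HFD G14.5 knockout replicate 1, 0 without HFD G14.5 knockout replicate 2 and 1 without HFD G14.5 wild-type replicate 2.

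Wild-type mice at G14.5 on the high-fat and the standard diet were compared to ask what the diet alone does. Diet moved 9 genes up and 21 down. The transcription factor Mlxipl, which responds to glucose, rose by 0.91 (SE 0.18, n = 2 each), and Hopx (-1.36) and Pam, which amidates peptide hormones (-1.19), fell. The δ-cell genes Sst, at 508 ± 533 against 76.8 ± 6.80 CPM (adjusted p 0.0432, 0.0584 with the replicate block, 0.527 without HFD G14.5 wild-type replicate 1, 0.111 without SD G14.5 wild-type replicate 1 and 0.313 without SD G14.5 wild-type replicate 2), and Rbp4 (2.13) were higher. With the replicate block 7 genes passed, and Mlxipl (adjusted p 0.057), Hopx (0.0641) and Rbp4 (0.0584) did not. The 638 genes lower at G14.5 in the time course had a median log2 fold change of 0.23 (adjusted p 0.0323) and the 916 higher genes of -0.12 (adjusted p 0.17). The count was 1 without HFD G14.5 wild-type replicate 1, 2 without HFD G14.5 wild-type replicate 2 and 1 without SD G14.5 wild-type replicate 2.

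Islets cultured in maternal serum and in normal serum were compared to ask whether serum alone brings about the gestational state. In the A485 table Prlr rose by 1.01 (SE 0.15, adjusted p 0.0139) and Tph1 to 9.14 ± 5.18 from 0.209 ± 0.127 CPM (adjusted p 0.0364, 0.171 without MS control replicate 1, 0.0734 without NS control replicate 1 and 0.115 without NS control replicate 2), n = 2 each. In the nifuroxazide table Prlr rose by 1.96 (SE 0.14) and Tph2 by 4.15 (adjusted p 0.00751, 0.0996 without NS control replicate 1), and Tph1 did not pass (2.38, adjusted p 0.18). Cish (3.92 and 4.28), Socs2 (2.57 and 1.99) and Chgb (2.79 and 1.85) rose in both tables. In all 33 genes were shared among those higher, against 0.431 by chance. The lactogen list rose in the A485 table (7 of 20 higher and 0 lower, 14 and 1 adjusted over the list alone, fry adjusted p 0.00367) and in the nifuroxazide table (7 of 20 higher and 0 lower, 11 and 0 adjusted over the list alone, fry adjusted p 0.00082). In all 70 and 80 genes were higher and 19 and 58 lower. Ins2 (-0.88) fell in the A485 table, and Ucn3 (-0.88) and Chga (-1.04) in the nifuroxazide table. There the cell cycle list rose (1 of 22 higher and 0 lower, 13 and 0 adjusted over the list alone, fry adjusted p 0.00484) and the exocytosis list fell (1 of 20 higher and 3 lower, 1 and 6 adjusted over the list alone, fry adjusted p 0.00351). The δ-cell markers summed to 294.8 CPM in maternal and 1563 ± 1412 in normal serum of the A485 table, Sst falling, and Ttr and C1qa fell in the nifuroxazide table. In the A485 table the count was 207 without MS control replicate 1, 55 without MS control replicate 2 and 43 without NS control replicate 1. In the nifuroxazide table the count was 67 without NS control replicate 1 and 77 without NS control replicate 2.

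A485, an inhibitor of the acetyltransferases p300 and CBP, was compared with vehicle in both sera to ask which genes need acetylation. It lowered more genes than it raised: 271 against 78 in normal serum and 352 against 95 in maternal serum, and more genes were lowered in both than the 7.04 due by chance (Fisher p 1.3e-177). Ins1 fell in normal serum (-1.29, SE 0.11) and in maternal serum (-1.11, SE 0.11, adjusted p 0.235 with limma on mean deposited normalized values). Ins2 (-0.74 and -0.71, the latter with adjusted p 0.716 with limma on mean deposited normalized values and 0.105 without MS A485 replicate 1), Slc2a2 (-0.999 and -1.61), Ero1lb (-1.51 and -1.66) and the acetyl-CoA enzyme Acly (-0.92 and -1.06) fell in both. Prlr fell in maternal serum (-0.94, adjusted p 0.00819), where Tph1 did not pass (-2.37, adjusted p 0.148). The immediate-early genes Fos (1.08 and 0.84) and Junb (1.08 and 0.94) and Rgs2 (1.42 and 2.27) rose in both, and Crebbp, which encodes CBP, rose in maternal serum (0.70). In maternal serum the lactogen list fell (0 of 20 higher and 4 lower, 0 and 9 adjusted over the list alone, fry adjusted p 0.00972). So did β-cell identity genes (0 of 20 higher and 5 lower, 0 and 12 adjusted over the list alone, fry adjusted p 0.0233, 0.0653 without MS A485 replicate 1). Of the genes higher at G14.5 in the time course, 85 were lowered by A485 in maternal serum, against 23.6 by chance, and 55 in normal serum, against 18.2. Markers of α, δ, ductal and immune cells fell with A485 in both sera, among them Gc, Pdyn, Krt18, Krt8 and C1qa. Of 29 hepatocyte markers 5 fell and 1 rose in maternal serum (median -1.565). The effect differed between sera for 1 gene, Nptx2 (4.34, adjusted p 0.045, 0.0508 with RLE size factors, 0.106 without NS A485 replicate 1 and 0.131 without NS A485 replicate 2). In normal serum the count was 61 without NS A485 replicate 1, 55 without NS A485 replicate 2 and 213 without NS control replicate 1. In maternal serum the count was 163 without MS A485 replicate 1 and 221 without MS A485 replicate 2. For the interaction the count was 3 without MS A485 replicate 2, 21 without MS control replicate 1, 2 without MS control replicate 2 and 3 without NS control replicate 1.

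Nifuroxazide, an inhibitor of STAT3, was compared with vehicle in both sera to ask which genes need STAT signalling. It raised Trib3 (2.03 in normal and 2.64 in maternal serum), Ddit3 (2.71 and 1.83) and Nupr1 (2.10 and 2.09), n = 2 per group. In normal serum Ins1 (-0.87), Ins2 (-0.68), Pcsk1 (-1.40) and the STAT target Cish (-1.55) fell. Prlr fell in both sera (-0.73 and -0.82); its adjusted p was 0.0691 without NS nifuroxazide replicate 1, 0.0606 without NS nifuroxazide replicate 2 and 0.0927 without NS control replicate 2 in normal serum and 0.067 with limma on mean deposited normalized values, 0.0694 without MS nifuroxazide replicate 1 and 0.187 without MS nifuroxazide replicate 2 in maternal serum. In normal serum 268 genes changed, 42.2% of them higher, and in maternal serum 46 were higher and 48 lower. The lactogen list fell in normal serum (0 of 20 higher and 4 lower, 0 and 8 adjusted over the list alone, fry adjusted p 0.00261), as did the exocytosis list (0 of 20 higher and 5 lower, 1 and 7 adjusted over the list alone, fry adjusted p 0.00261). Markers Tmem27, Gc and Ttr of α cells fell and Try5 of acinar cells rose in normal serum. For the interaction edgeR called 0 of 13481 genes, with 886 at unadjusted p < 0.05 and 72 by DESeq2. The cell cycle and exocytosis lists each had a fry adjusted p of 0.0493. Both were at 0.0728 with RLE size factors, and at 0.145 and 0.137 with the replicate block. With 1 library left out the cell cycle list was above 0.05 each time (0.0621 to 0.306) and the exocytosis list each time (0.0621 to 0.306) except without NS control replicate 1. In normal serum the count fell without any 1 library. In maternal serum the count was 46 without MS nifuroxazide replicate 1 and 48 without MS nifuroxazide replicate 2. For the interaction the count was 22 without MS control replicate 1, 1 without MS control replicate 2, 6 without NS nifuroxazide replicate 2, 1 without NS control replicate 1 and 1 without NS control replicate 2.

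The genes called at G14.5 in the time course were followed in the other tables, which share no library with it. The gestation-up list had medians of 0.43, 0.45 and 0.45 in wild type of the Acss2, Stat3 and p300 tables (adjusted p 0.00106, 0.0075 and 0.0121). They were 0.34 on the high-fat diet (adjusted p 0.00554), and 0.22 and 0.24 with maternal serum (adjusted p 0.053 and 0.0075). In the Acss2, Stat3 and p300 tables the targeted gene was not called lower in knockout, so the need for it was not tested. At G14.5 the list had medians of 0.03, 0.01 and -0.07 in these knockouts (adjusted p 0.741, 0.971 and 0.741). In the G18.5 Acss2 knockout it had -0.19 (adjusted p 0.0509). With A485 in maternal serum it had a median of -0.24 (adjusted p 0.0509, 0.0464 with RLE size factors and 0.0291 with the replicate block), in normal serum -0.21 (adjusted p 0.0682) and for the interaction -0.02 (adjusted p 0.863). With nifuroxazide in maternal serum it had -0.12 (adjusted p 0.0448, 0.0749 with the replicate block and 0.053 to 0.126 without any 1 library), in normal serum -0.06 (adjusted p 0.125) and for the interaction -0.06 (adjusted p 0.502). Limited to 2-fold changes it had 0.77 for serum in the A485 table (adjusted p 0.0139), -0.69 and -0.49 for A485 in maternal and normal serum (0.0153 and 0.0378), -0.47 and -0.28 for nifuroxazide (0.00139 and 0.0031) and -0.07 for the G18.5 Acss2 knockout (0.606). Without G14.5 wild-type replicate 1 it was not called in p300 wild type.

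**Figure D5:**
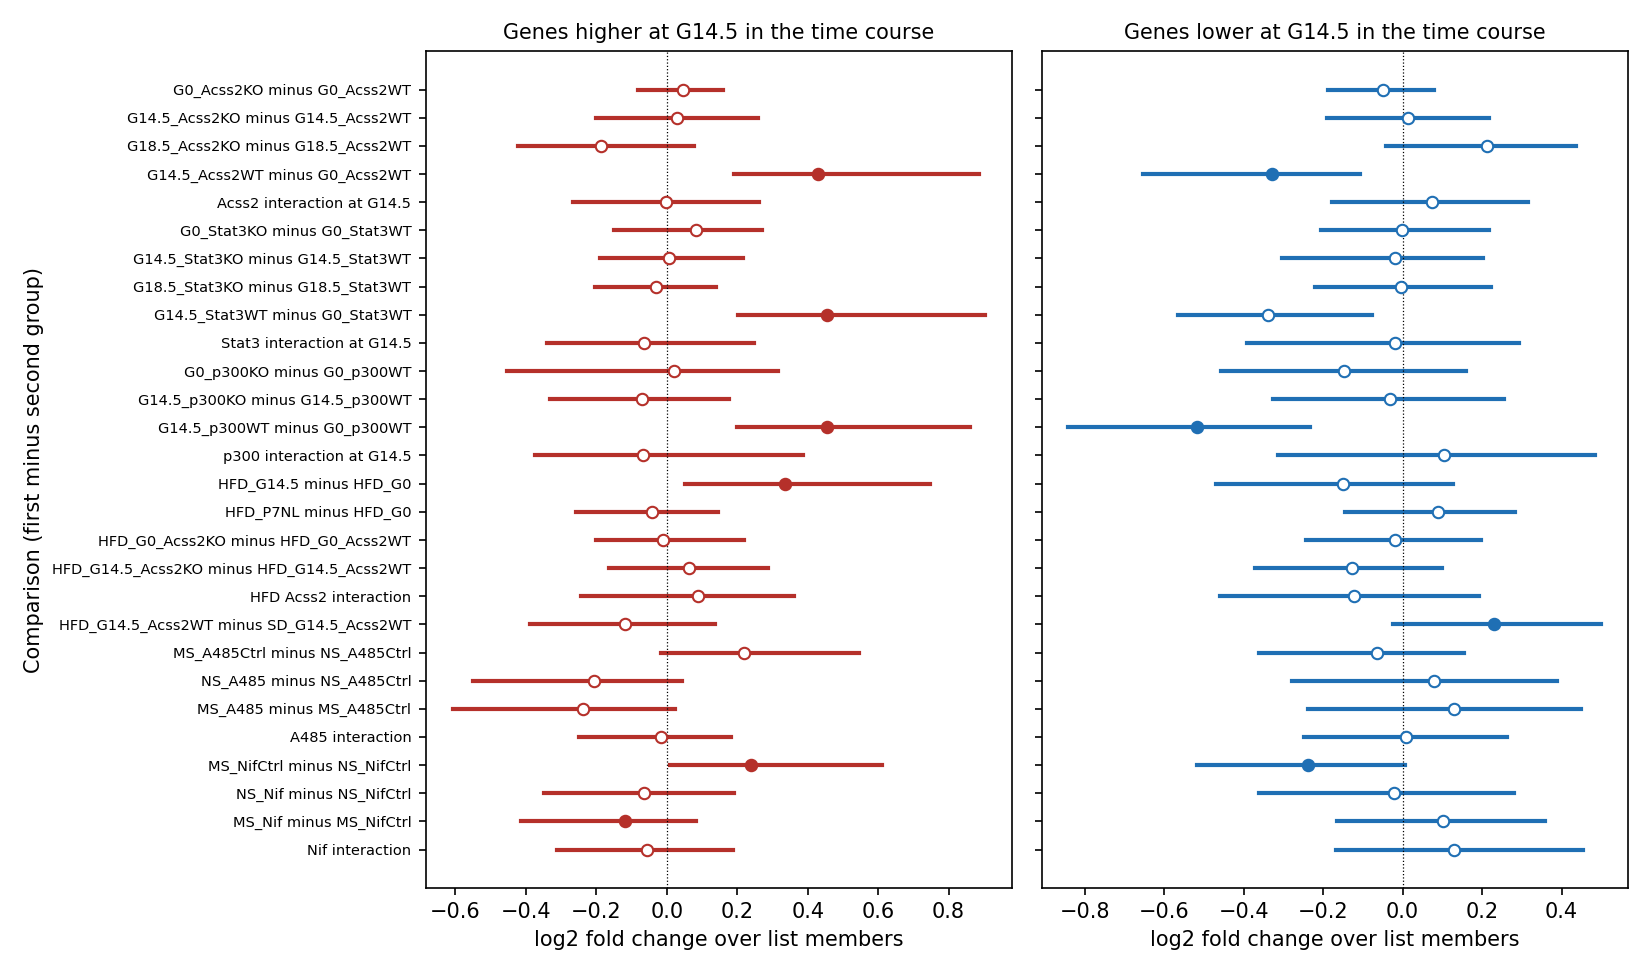
Median log2 fold change of the time-course gestation-up and gestation-down lists in each comparison of the other tables; filled circles have a fry adjusted p below 0.05, open circles not, and lines are quartiles. The up list lies at 0.43 in wild-type G14.5 of the Acss2 table and at 0.03 in its G14.5 knockout comparison.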

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

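All results in this part were picked out by a test of the difference between 2 effects, knockout at G14.5 against knockout at G0, or a drug in maternal against normal serum. The predictions weighed below were written before their tests were run. The shares of changed genes near Pianp at G14.5, its p300 levels and the correlation without p300 libraries were chosen after the results had been seen.

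In the Acss2 table the knockout effect differed between stages for Sftpd (-5.455), Chac1 (-2.011) and P2ry1 (-1.518, log2 scale). Sftpd stood at 0.697 CPM in G0 knockout and 0.0144 CPM in G0 wild type, and at 90.1 and 89.5 CPM at G14.5, so the difference lies in reads near the floor at G0. Chac1 and P2ry1 differed at G14.5. In the A485 table the effect of A485 on Nptx2 differed between sera by 4.343: it stood at 1.88 against 93.7 CPM in normal serum and at 24.8 against 60.5 CPM in maternal serum. In the nifuroxazide table the effect on the cell cycle list (fry adjusted p 0.0493) and on the exocytosis and excitability list (0.0493) differed between sera, but not with RLE size factors (0.0728 for both) or the replicate block (0.145 and 0.137), nor without 1 library in 8 and 7 of 8 settings. In the high-fat-diet table the knockout effect differed for Ivd (-2.473), which stood at 105.6 and 70.05 CPM in knockout and wild type at G0.

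Pianp differed between stages in the high-fat-diet table (15.25), from 0 CPM in G0 knockout to 32.3 CPM in G14.5 knockout. Over both Acss2 tables it stood at 23.23 to 41.78 CPM over plain library sizes in 4 of 10 knockout libraries, with reads in 62% to 83% of their cells, and at 0.3007 at most in wild type. A few cells were excluded as the source, since the top 3 cells held at most 18.26% of the reads. Loss of Acss2 itself remained open: 6 knockout libraries had less than 1 CPM, a bound set beforehand against it, but the 4 others were all those of G18.5 and of G14.5 on the high-fat diet, so an effect that depends on stage or diet is not ruled out. Of the p300 libraries, 3 of 4 wild-type and 4 of 4 knockout passed 10 CPM on the same sizes, with 0.07558 and 37.68 in G0 wild type. High Pianp thus occurred without loss of Acss2, which argues against that loss as its only source. A stretch of chromosome 6 that differs between animals remained open: 11.96% of the 92 other genes within 5 Mb had an unadjusted p under 0.05 at G18.5, against 10.9% elsewhere (Fisher p 0.421), 8.791% against 8.444% at G14.5 on the high-fat diet (Fisher p 0.507), and 20.65% against 10.39% at G14.5 on the standard diet (Fisher p 0.00275), where Pianp was not raised. Gdf3 and Apobec1, which also rose at G18.5, and Grcc10 lie on the same chromosome, and no biological explanation was tested.

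In the p300 table the effect differed for Tph1 (8.517), P2ry1 (2.552), Cited2 (2.07), Tagap (10.37), Rec8 (5.916), Rsad2 (6.041), Tmem2 (2.702), Cd59a (-2.694) and Il1r1 (1.51). The value of Tph1 rests on 0 CPM in G0 knockout against 0.632 CPM in G0 wild type. At G0 P2ry1, Cited2, Rec8, Rsad2, Tmem2 and Il1r1 were lower and Cd59a higher in knockout, and at G14.5 no gene passed. Rec8 stood at 0.338 against 26.02 CPM at G0 and 22.02 against 27.9 at G14.5. Wild-type libraries that stand apart were weighed for the genes lower in G0 knockout. The median log2 ratio to 6 other wild-type G0 libraries was 0.4617 for p300 wild type and -0.9043 for knockout. Knockout to p300 wild type was -1.449. For the genes higher these were -0.2893, 0.783 and 1.085. The p300 libraries had selected these genes, which alone can give such signs, so that explanation remained open. Depth remained open as well: the median correlation of level with reads per cell over wild-type G0 libraries was 0.3827, which met the bound set beforehand against it. Without the p300 libraries it was 0.0935, and the deepest wild-type library had 1068056 reads per cell against at least 1522785 in knockout. Loss of p300 was not told apart from either.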

How the results depend on the processing

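Single libraries set most limits: with 2 replicates in most groups, leaving 1 out left a lone sample, assumed to vary like the other groups. Of 4379 tests with 1 library left out on named genes past the threshold, 2796 kept the call, 1583 lost it and none reversed. Of 1676 on named genes short of it, 52 passed. Calls kept and lost were 1030 and 11 with DESeq2, 202 and 58 with limma on the deposited normalized values, 1037 and 4 without the filter on low counts, 1033 and 8 with RLE size factors, and 258 and 2 without cells over 5% in other hormones. No named gene reversed under any of them. Replicate numbers do not pair the samples: correlations of deviations from the group mean between libraries of the same number ran from -0.0908 to 0.143 over 37 comparisons, with a median of 0.00705. With the number as a block, 983 calls were kept and 58 lost. The limma alternative was not run for the p300 table, and for the Stat3 table only with libraries that have complete values. Depth limits genes at few reads, where CPM at 0 reads gives no fold. The alternatives below on at least 12 cell cycle genes, on the block for the lists and on lists with 1 library left out were chosen after the data were seen. Counts written with an exponent are rounded to 2 digits. The cause was not tested for any value below, except that fewer samples or more genes tested go with the setting.

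Without the filter on low counts the number of genes changed was 385 for G3.5, 549 for G5.5, 546 for G6.5, 817 for G10.5, 356 for P2NL, 428 for P7NL, 294 for P14NL, 166 for P2 L, 288 for P7 L, 370 for P14 L, 87 for G0 Acss2 knockout, 269 for G14.5 Acss2 knockout, 353 for G18.5 Acss2 knockout, 868 for Acss2 wild type, 93 for Acss2 interaction, 1.2e+02 for G0 Stat3 knockout, 120 for G14.5 Stat3 knockout, 97 for G18.5 Stat3 knockout, 509 for Stat3 wild type, 1.2e+02 for Stat3 interaction, 868 for G0 p300 knockout, 315 for G14.5 p300 knockout, 1001 for p300 wild type, 245 for p300 interaction, 772 for HFD G14.5, 90 for HFD P7NL, 1.0e+02 for HFD G0 Acss2 knockout, 1.3e+02 for HFD G14.5 Acss2 knockout, 84 for HFD Acss2 interaction, 327 for HFD against SD, 492 for serum (A485 table), 1143 for A485 in NS, 1206 for A485 in MS, 79 for A485 interaction, 445 for serum (nifuroxazide table), 753 for nifuroxazide in NS, 389 for nifuroxazide in MS and 1.3e+02 for nifuroxazide interaction.

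With DESeq2 it was 327 for G3.5, 579 for G5.5, 498 for G6.5, 1392 for G8.5, 829 for G10.5, 1186 for G12.5, 1152 for G18.5, 239 for P2NL, 293 for P7NL, 217 for P14NL, 48 for P2 L, 219 for P7 L, 251 for P14 L, 6 for G0 Acss2 knockout, 165 for G14.5 Acss2 knockout, 356 for G18.5 Acss2 knockout, 830 for Acss2 wild type, 33 for Acss2 interaction, 84 for G0 Stat3 knockout, 64 for G14.5 Stat3 knockout, 30 for G18.5 Stat3 knockout, 459 for Stat3 wild type, 49 for Stat3 interaction, 856 for G0 p300 knockout, 294 for G14.5 p300 knockout, 1014 for p300 wild type, 180 for p300 interaction, 716 for HFD G14.5, 34 for HFD P7NL, 78 for HFD G0 Acss2 knockout, 79 for HFD G14.5 Acss2 knockout, 43 for HFD Acss2 interaction, 394 for HFD against SD, 354 for serum (A485 table), 1010 for A485 in NS, 1071 for A485 in MS, 11 for A485 interaction, 415 for serum (nifuroxazide table), 777 for nifuroxazide in NS, 364 for nifuroxazide in MS and 72 for nifuroxazide interaction.

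With the replicate block it was 3 for G14.5 Stat3 knockout, 95 for HFD G14.5, 2 for HFD P7NL, 7 for HFD against SD, 1.4e+02 for serum (A485 table) and 4 for A485 interaction. With RLE size factors it was 0 for A485 interaction. With limma on the deposited normalized values it was 5 for G14.5 Acss2 knockout and 0 for G14.5 Stat3 knockout. Without cells over 5% in other hormones it was 2 for G14.5 Stat3 knockout.

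With 1 library left out the lowest and highest numbers were 22 to 93 for G3.5, 43 to 280 for G5.5, 86 to 1.6e+02 for G6.5, 363 to 637 for G8.5, 1.4e+02 to 306 for G10.5, 293 to 621 for G12.5, 775 to 2027 for G14.5, 407 to 765 for G16.5, 348 to 717 for G18.5, 15 to 61 for P2NL, 1 to 54 for P7NL, 3 to 95 for P14NL, 0 to 58 for P2 L, 41 to 63 for P7 L, 48 to 1.2e+02 for P14 L, 1 to 5 for G0 Acss2 knockout, 2 to 40 for G14.5 Acss2 knockout, 7 to 83 for G18.5 Acss2 knockout, 177 to 388 for Acss2 wild type, 1 to 28 for Acss2 interaction, 2 to 28 for G0 Stat3 knockout, 0 to 12 for G14.5 Stat3 knockout, 2 to 7 for G18.5 Stat3 knockout, 78 to 1.5e+02 for Stat3 wild type, 0 to 12 for Stat3 interaction, 68 to 251 for G0 p300 knockout, 1 to 32 for G14.5 p300 knockout, 1.5e+02 to 567 for p300 wild type, 1 to 55 for p300 interaction, 7 to 349 for HFD G14.5, 0 to 4 for HFD P7NL, 0 to 91 for HFD G0 Acss2 knockout, 0 to 5 for HFD G14.5 Acss2 knockout, 0 to 20 for HFD Acss2 interaction, 1 to 37 for HFD against SD, 43 to 207 for serum (A485 table), 55 to 378 for A485 in NS, 163 to 404 for A485 in MS, 1 to 21 for A485 interaction, 67 to 160 for serum (nifuroxazide table), 1.2e+02 to 212 for nifuroxazide in NS, 46 to 1.3e+02 for nifuroxazide in MS and 0 to 22 for nifuroxazide interaction.

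For the genes higher at G14.5 in the time course the median log2 fold change was with the list limited to 2-fold changes -0.53 for G0 p300 knockout (adjusted p 0.0378), 0.77 for serum (A485 table) (adjusted p 0.0139), -0.49 for A485 in NS (adjusted p 0.0378), -0.69 for A485 in MS (adjusted p 0.0153) and -0.28 for nifuroxazide in NS (adjusted p 0.0031). It was with RLE size factors -0.25 for A485 in MS (adjusted p 0.0464). It was with the replicate block 0.22 for serum (A485 table) (adjusted p 0.0347), -0.21 for A485 in NS (adjusted p 0.0412), -0.24 for A485 in MS (adjusted p 0.0291) and -0.12 for nifuroxazide in MS (adjusted p 0.0749). With 1 library left out it ran over -0.023 to 0.13 for G0 Acss2 knockout, -0.12 to 0.081 for Acss2 interaction, 0.37 to 0.59 for p300 wild type and -0.16 to -0.099 for nifuroxazide in MS. For the genes lower there the median log2 fold change was with the list limited to 2-fold changes 0.40 for G18.5 Acss2 knockout (adjusted p 0.0193), -0.24 for HFD G14.5 (adjusted p 0.0432) and -0.13 for serum (A485 table) (adjusted p 0.0392). It was with RLE size factors -0.36 for Stat3 wild type (adjusted p 0.0471). With 1 library left out it ran over 0.076 to 0.27 for G18.5 Acss2 knockout, -0.37 to -0.28 for Acss2 wild type, -0.23 to -0.028 for G0 p300 knockout, -0.58 to -0.39 for p300 wild type, -0.21 to -0.13 for HFD G14.5, 0.17 to 0.31 for HFD against SD and -0.29 to -0.18 for serum (nifuroxazide table). The Acss2 interaction of the higher genes reversed without G0 wild-type replicate 1 (0.0812, adjusted p 0.0468), and the G0 p300 knockout turned negative with the list limited to 2-fold changes.

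The share of cells with cell cycle transcripts was, with at least 2 genes, 77.95% for G0, 83% for G10.5, 88.9% for G12.5, 87.97% for G14.5, 87% for G18.5, 79.15% for G3.5, 78% for G5.5, 88.5% for G6.5, 87.55% for G8.5, 77.03% for P14L, 77.8% for P14NL, 85.8% for P2L, 81.8% for P2NL, 83.95% for P7L and 82.25% for P7NL. With at least 12 genes it was 2.4% for G0, 3.1% for G10.5, 4.15% for G12.5, 2.133% for G14.5, 2.2% for G16.5, 1.467% for G18.5, 2.85% for G3.5, 1.7% for G5.5, 2.95% for G6.5, 3.3% for G8.5, 1.067% for P14L, 0% for P14NL, 1.45% for P2L, 1% for P2NL, 0% for P7L and 0% for P7NL. Without thinning it was 65.15% for G10.5, 47.65% for G5.5, 61.6% for G6.5, 57% for P14NL and 56.15% for P7L.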

Other observations

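The tests on liver transcripts in this part were predicted before they were run. The genes of the first paragraph were picked after their values had been seen.

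Ivd, an enzyme of leucine breakdown, rose in gestation and lactation, by 2.48 at G10.5 against G0 and by 1.77 on day 2 in lactating against non-lactating mice (log2 scale), and fell by 1.88 with loss of Acss2 at G14.5 on the high-fat diet. Ivd, Chac1 and Acss2 all lie on chromosome 2.

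At G8.5 hepatocyte markers summed to 906.6 and 653.7 CPM in the 2 libraries, against 47.25 and 47.38 CPM at G0 and 26.51 and 39.31 CPM at G10.5. RNA or cells of the liver in these libraries fits: the 22 markers not seen before the list was written had a median log2 fold change of 6.308. The top 3 cells as the only holders were excluded, since they held 45.79% of the reads at most. That 100% of cells had some does not show spread, since the marker Ambp passed 10 CPM at G0. Deeper sequencing was excluded, since G10.5 held 4.218% of the level of G8.5. Free RNA in the cell suspension was not tested, nor was any biological explanation. The same markers summed to 1020 CPM in G14.5 wild-type replicate 2 of the Acss2 table and 828.4 CPM in that of the Stat3 table, and to 158.7 and 431.7 CPM in the maternal serum controls of the A485 table.

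Rgs2 stood at 27.7 CPM at G0 and 174.5 CPM at G3.5 in the time course. In wild type of the Acss2, Stat3 and p300 tables it stood at 315.1, 320.6 and 449.1 CPM at G0 and fell at G14.5. Knockout of p300 at G0 lay below 27.7 CPM.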
